A study of Mus musculus with 6 samples.

How the data were processed

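RNA was extracted from soleus muscle of male C57BL/6N mice and made into strand-specific cDNA libraries, per the labels' protocols. The series holds 6 samples in 2 groups taken from the sample labels: 3 samples labelled as a knockout of Hectd1 in skeletal muscle (mKO) and 3 labelled wild type. Reads were aligned with STAR 2.7.3a to GRCm38.p6 and assigned to genes with featureCounts 2.0.0, per the submitters' processing notes. Per the file headers, featureCounts took the libraries as reverse stranded, counted read pairs as fragments and counted a fragment that overlaps several genes for each of them. Genes that overlap on the same strand therefore share fragments, and fragments that map to several places were not counted, which lowers and blurs the values of near-identical copies.

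The deposited gene count table has 6 library columns whose codes match no label of any sample. None of them was used in any step, because a column could have been given to a genotype only by guessing. The depth per sample is thus not given here, and no value per library, no SD and no test on counts was made. Of that table, the deposited gene models and exonic lengths were used, for 51912 genes, to look for genes that share exonic bases with Hectd1 and for the length check.

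All levels and differences come from the authors' deposited table, a comparison of mKO over wild type by its name. It was made with DESeq2, per the submitters' processing notes, whose version is not given in the sources used here. Its mean normalized count is a signal value that the authors made by dividing counts by size factors and averaging over libraries, so it is not a count. The log2 fold change and its standard error (SE) are those the authors deposited. The Wald statistic is a score per gene as deposited by the authors. The p-value and the adjusted p are deposited too, and an empty adjusted p stayed empty. The median SE was 0.157 in the lowest decile of the mean normalized count, 0.24 in the third decile and 0.0981 in the highest. An SE that narrows at the lowest levels is what shrinkage of fold changes toward 0 gives, so fold changes of low genes are read as understated. Whether the authors shrank them is not given in the sources used here.

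The table had 16482 rows for 16410 distinct genes. 70 genes were listed more than once with identical values and were used once. 14019 genes had an adjusted p, and 2391 did not, the highest mean normalized count among these being 8.78. The ratio of the smallest adjusted p to its p corresponds to 15592 genes in the authors' adjustment, so 1573 genes behind it are not in the rows used here. All genes matched the GENCODE M21 annotation of GRCm38 by identifier, and 88.5% had the same start and end. Symbols and coordinates are those of the deposited table, on GRCm38.

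A gene was called risen or fallen at a deposited adjusted p under 0.05. 39 gene lists were fixed before the data were examined, for sarcomere and muscle programmes, stress, metabolism, pathways linked to Hectd1, other cell types and collection effects. Each list with at least 3 tested members was compared with the other genes by cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on the deposited Wald statistics with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. This, with the authors' own calls per gene, stands in for the tests on counts that had been planned. The median fold change of a list was also placed among those of 10000 random lists matched on mean normalized count. 7 further lists were chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest, including permutation tests with 100000 resamples between lists.

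The named genes follow a rule fixed before the data were examined: Hectd1, the 10 largest rises and 10 largest falls, the 5 smallest p-values per direction outside these, and up to 4 members per list with the smallest p among those past the threshold, or else 1 member given as values. Symbols that are provisional were left out of the largest changes. The rule also asked for a mean of at least 2 CPM and for libraries of the groups that do not overlap. Neither could be applied without library values, so the first was applied to the mean normalized count, scaled so that the table sums to that of a CPM column, and the second was dropped. It named 139 genes.

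The list test was tested on simulated data made for the comparison of mKO over wild type with its 14019 genes. In 20 simulated data sets it found 25% of lists shifted by a mean Wald statistic of 0.5, 60% at 1 and 100% at 2 and at 3. It called 0.84% of lists with no shifted member. On 100 permutations of the real statistics, 3.5% of lists had an unadjusted p under 0.05. The simulated statistics were independent and standard normal, and permutation also breaks any correlation between genes. The deposited statistics are wider (inflation factor of their square 2.57), and members of a list may move together. These rates may therefore not hold for the real lists. In a single further draw of such independent statistics, the Benjamini-Hochberg adjustment recovered 100% of 200 genes shifted by 6 in either direction, with 6 false calls. Shifts this large are recovered almost by construction, so this does not measure recovery or false calls in the real data.

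The alternatives tried were other adjusted p thresholds, a fold change minimum of 1.5, a mean normalized count of at least 100, protein-coding genes alone, an adjustment over all listed genes, an inflation-corrected statistic, ranks, a preset correlation of 0.05, lists without shared members, and the statistic after a trend on exonic length and GC content was removed.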

Results

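The data describe the transcriptome of the mouse soleus, a calf muscle that in mice holds many slow-twitch fibres. RNA was sequenced from 6 male C57BL/6N samples. 3 of them are labelled as a knockout of Hectd1 in skeletal muscle (muscle knockout, mKO) and 3 as wild type. Hectd1 encodes a ubiquitin ligase of the HECT family, an enzyme that attaches ubiquitin to other proteins. The comparison asks which transcripts differ in soleus when this ligase is removed from muscle. The series title ties that loss to sarcomere assembly and to a myopathy with desmin and nemaline features. All values below come from the authors' deposited table of mKO over wild type, which gives 1 fold change, standard error (SE) and adjusted p per gene and no value per sample. The depth of each sample is therefore not given here. The labels do not tie samples to separate animals, although the series text speaks of animals. The deposited p-values per gene therefore measure only the spread between these 6 samples. The p-values of gene lists and of permutation tests take genes as their units and measure no spread between samples. A gene is said to have risen or fallen when its deposited adjusted p is under 0.05, and the direction is always that of the libraries labelled mKO relative to those labelled wild type.

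The targeted gene came first, because it checks the labels. Hectd1 (ENSMUSG00000035247, chromosome 12, 51743722 to 51829536, minus strand, GRCm38) was higher, not lower, on the mKO side of the authors' deposited table. Its log2 fold change was 0.58 (SE 0.10), a 1.49-fold higher level at a mean normalized count of 8047, with an adjusted p of 2.02e-07. This goes against the label of a knockout. The counts cover every annotated exon of the gene, so exons that a conditional deletion leaves in place still yield fragments, and the table cannot show the deleted part on its own. No other annotated gene shared exonic bases with Hectd1 on the same strand. The direction of each difference reported here rests on the name given to the comparison, and the targeted gene does not bear that direction out.

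Of 14019 genes with an adjusted p, 969 rose and 913 fell on the mKO side of the authors' deposited table, 1882 or 13.4% in all. The changes were mostly moderate: 147 of these genes moved by a log2 fold change of at least 1, 108 of them upward and 39 downward. The largest rise among genes above the level minimum was that of Myh3, the embryonic myosin heavy chain (chromosome 11, 67078300 to 67102291), at log2 2.90 (SE 0.14, adjusted p = 9.16e-89), a 7.46-fold higher level in the authors' deposited table (0.134-fold if the contrast were turned). Sarcolipin (Sln), a small inhibitor of the calcium pump of the sarcoplasmic reticulum, rose by log2 2.35 (SE 0.13), and Ryr3, a calcium release channel, by 2.14 (SE 0.18) in the authors' deposited table. The other 7 of the 10 largest rises there were the cell adhesion gene Nrcam (2.44), the phosphatase gene Dupd1 (2.19), Epn3 (2.17), Ndrg4 (2.04), the retinol carrier Rbp4 (2.03), the keratin Krt80 (1.92) and the myosin light chain Myl6b (1.89), with SEs from 0.12 to 0.23. Rises with the smallest p outside this group in the authors' deposited table were those of Klhl13 (1.88), the mitochondrial carrier Ucp2 (1.66), Tppp3 (1.64), Clic4 (1.02) and the major vault protein Mvp (1.02).

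Among the falls, Ppp1r14bl had the largest in the authors' deposited table above the level minimum, at log2 -1.88 (SE 0.21). It was followed there by Arrdc2 (-1.69), the actin-related gene Actr3b (-1.67), the mitochondrial folate enzyme Mthfd2 (-1.64), the transcription factor Dach2 (-1.55), the iron exporter Slc40a1 (-1.54), Galnt5 (-1.51), Tspan8 (-1.47), the lactate transporter Slc16a3 (-1.40) and Smco1 (-1.29), with SEs from 0.14 to 0.22. The smallest p-values among the other falls in the authors' deposited table belonged to 3 fast-fibre sarcomere genes, Tnni2, Tnnt3 and Mylpf, to the oxygen-sensing hydroxylase Egln3 (-1.19, SE 0.10), which lies within 5 Mb of Hectd1, and to the stress-response transcription factor Atf5 (-1.05, SE 0.10). The count of changed genes depends on the threshold: 1192 passed an adjusted p of 0.01, and 658 had in addition to 0.05 a fold change of at least 1.5. After division of the Wald statistic by the square root of its inflation factor of 2.57, 326 genes passed.

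**Figure D1:**
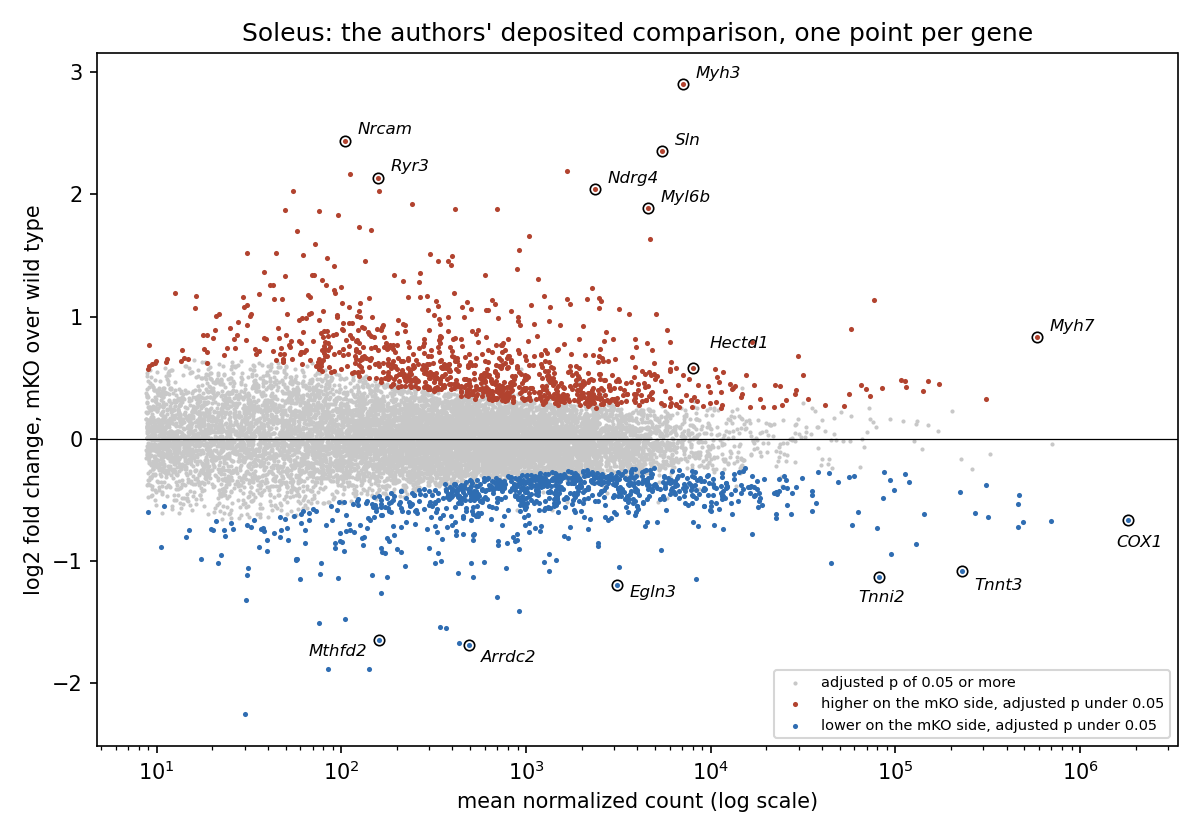
Log2 fold change of each gene with an adjusted p (mKO over wild type, vertical axis) against its mean normalized count (horizontal axis, log scale), from the authors' deposited table. Red and blue points are the 969 genes that rose and the 913 that fell on the mKO side. Circled genes are named, among them Hectd1 at 0.58 and Myh3 at 2.90.

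Of the 39 gene lists fixed before the data were examined, 38 had at least 3 tested members, and 19 of these stood apart from the other genes as a set (limma's cameraPR on the deposited Wald statistics, preset correlation 0.01, Benjamini-Hochberg over lists). 12 were higher and 7 lower on the mKO side. A correlation estimated per list needs values per sample and could not be had. With a preset correlation of 0.05 in place of 0.01, 16 lists passed. The calls lost were those of the Z-disc list (adjusted p = 0.131), the thick filament list (adjusted p = 0.109) and the fibro-adipogenic progenitors (adjusted p = 0.0943). With the inflation-corrected statistic, each member named below by its p lost its call in the costamere, atrophy, autophagy, ribosomal protein, fatty acid, retinoic acid, p53, oxidative stress, fibro-adipogenic progenitor, macrophage, endothelial and circadian clock lists. Elsewhere the same held for Nrap, Myl4, Mymk, Ankrd1, Ankrd23, Runx1, Rgs5, Myh11, Adipoq, Plin1, Jun, Fosl2 and Btg2.

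**Figure D2:**
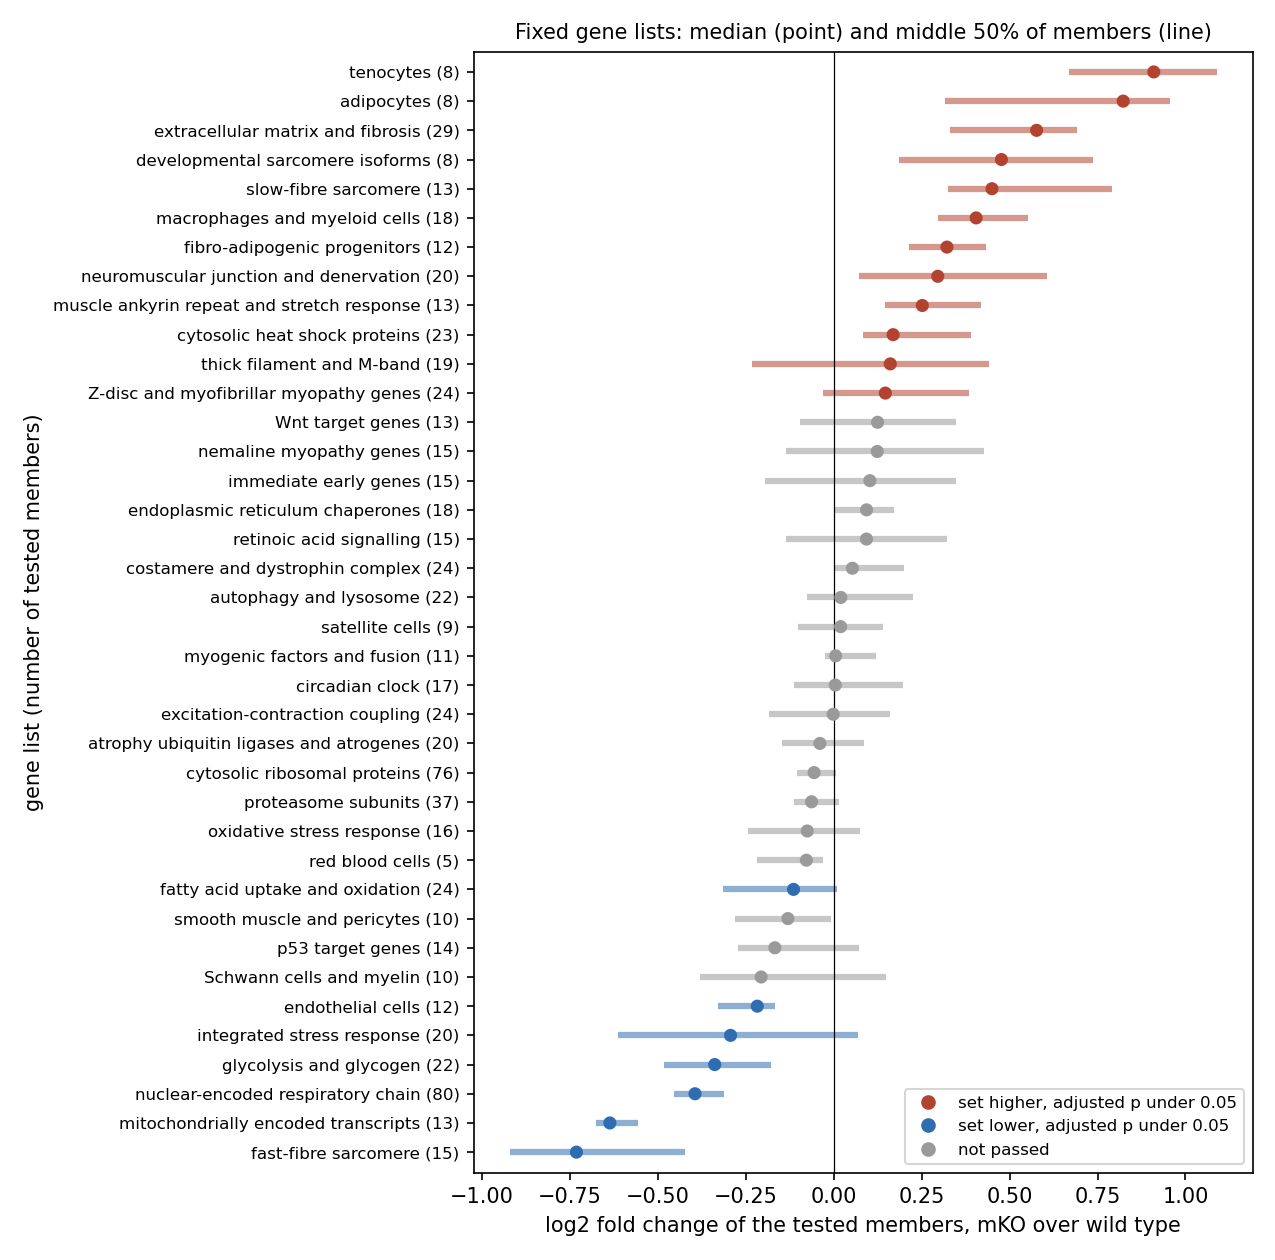
Median log2 fold change (point) and range from the lower to the upper quartile (line) of the tested members of each of 38 gene lists, mKO over wild type, from the authors' deposited table; the number of tested members follows each name. Red lists were higher and blue lists lower as a set, from tenocyte markers at a median of 0.91 to the fast-fibre sarcomere at -0.73.

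Sarcomere transcripts of slow fibres were higher and those of fast fibres lower on the mKO side. Of 13 slow-fibre genes, 10 rose, 1 fell and 2 did not pass (11 rose and 1 fell adjusted over the list alone), with a median of log2 0.45 and an adjusted p of 6.72e-18 for the list. Myl6b rose by 1.89 (SE 0.13), slow troponin I (Tnni1) by 0.90 (SE 0.08), the slow myosin heavy chain Myh7 by 0.83 (SE 0.09) and Myh7b by 0.79 (SE 0.10) in the authors' deposited table. The exception there was Myoz2, a calcineurin-binding Z-disc protein, which fell by 0.46 on the log2 scale (SE 0.08). Of 15 fast-fibre genes, none rose, 11 fell and 4 did not pass (13 fell adjusted over the list alone), with a median of -0.73 and an adjusted p of 1.08e-30. Fast troponin I (Tnni2, -1.13, SE 0.08), fast troponin T (Tnnt3, -1.08, SE 0.08), the fast regulatory light chain Mylpf (-1.01, SE 0.09) and Tpm1 (-0.86, SE 0.09) had the smallest p-values of these in the authors' deposited table. Among the fast myosin heavy chains there, Myh2 and Myh1 fell, at -0.46 (SE 0.09) and -0.43 (SE 0.11), while Myh4, at -0.38 (SE 0.19), did not pass. Myosin heavy chain genes are similar in sequence, and fragments that map to several places were not counted, so their values are less certain than those of other genes.

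**Figure D3:**
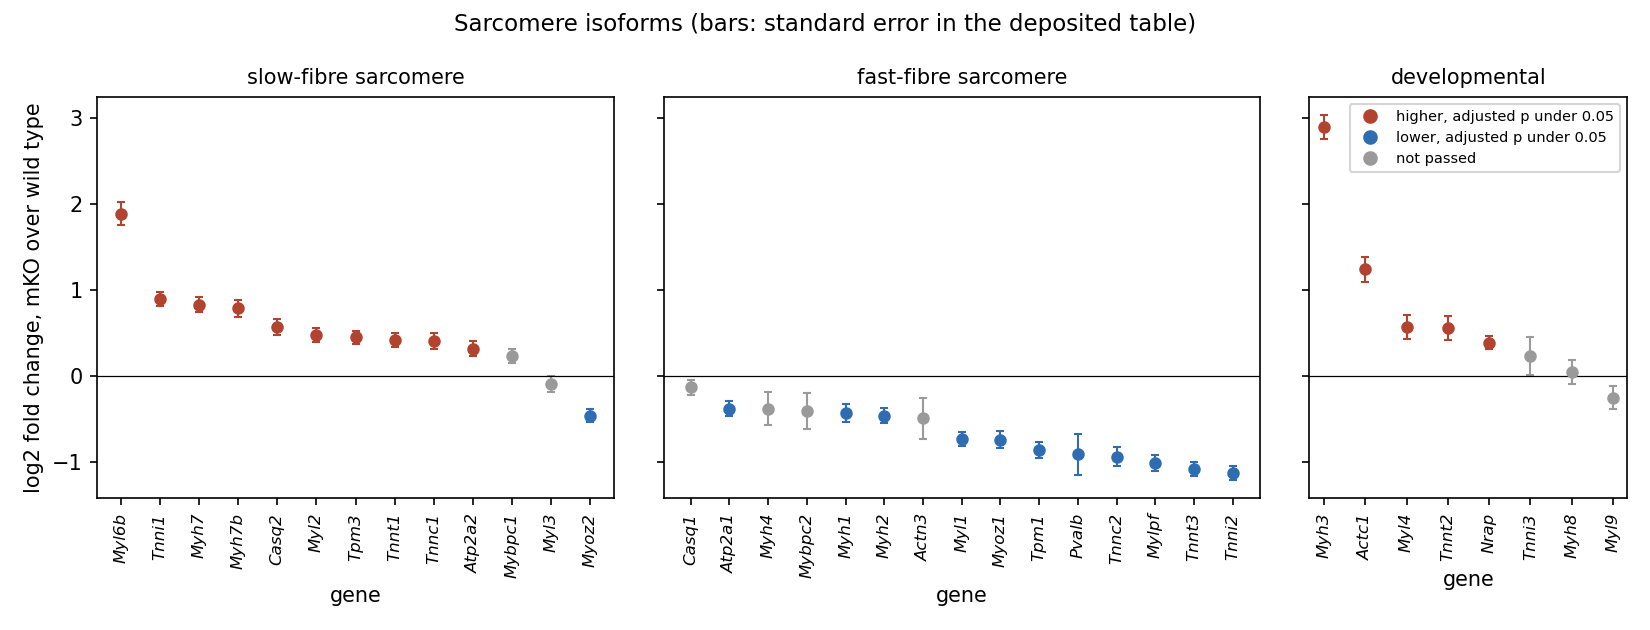
Log2 fold change (mKO over wild type) of each tested slow-fibre, fast-fibre and developmental sarcomere gene in the authors' deposited table, with bars of 1 SE. Red genes rose, blue genes fell and grey genes did not pass; Myh3 (2.90) and Myl6b (1.89) lie above the other genes, and Tnni2 (-1.13) lies lowest.

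Developmental isoforms were higher as well. Of 8 such genes, 5 rose, none fell and 3 did not pass (5 rose adjusted over the list alone), with a list adjusted p of 2.85e-11. On ranks, which give the large statistic of Myh3 less weight, the list still passed, at an adjusted p of 0.0112. Beside Myh3, cardiac alpha-actin (Actc1), which skeletal muscle makes before birth, rose by log2 1.24 (SE 0.14), Myl4 by 0.57 (SE 0.14) and Nrap by 0.39 (SE 0.08) in the authors' deposited table. The perinatal myosin heavy chain Myh8 was at 0.05 (SE 0.14) and did not pass. Myogenic factors did not stand apart as a set (adjusted p = 0.36): 2 of 11 rose, myogenin (Myog, 0.93, SE 0.16) and the fusion protein gene Mymk (0.65, SE 0.23), and 9 did not pass in the authors' deposited table (2 rose adjusted over the list alone). Myod1 was at -0.01 (SE 0.16) there. None of 9 satellite cell markers passed (none adjusted over the list alone; list adjusted p = 0.69), and the smallest p was that of Cdh15 at 0.29 (SE 0.11) in the authors' deposited table.

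Genes of nemaline myopathy, a disease of thin filaments, moved both ways. Of 15, 7 rose, 2 fell and 6 did not pass (7 rose and 3 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.098). It passed once the members shared with another list were left out (adjusted p = 0.0281). Ryr3 (2.14), the Kelch protein gene Klhl40 (0.63, SE 0.09) and the slow tropomyosin Tpm3 (0.45, SE 0.08) rose and Tnnt3 fell in the authors' deposited table, while nebulin (Neb, 0.12, SE 0.09) and skeletal actin (Acta1, -0.04, SE 0.09) did not pass. Of 24 genes of the Z-disc and of myofibrillar myopathy, 8 rose, 3 fell and 13 did not pass (9 rose and 3 fell adjusted over the list alone; list adjusted p = 0.032). This call was lost without the members shared with another list (adjusted p = 0.259), with a preset correlation of 0.05 (adjusted p = 0.131) and after the length and GC trend was removed (adjusted p = 0.0594). The co-chaperone gene Bag3 (0.51, SE 0.09) and Ldb3 (0.44, SE 0.08) rose, and Myoz1 (-0.74, SE 0.10) and Myoz2 fell in the authors' deposited table. Desmin (Des), which the series title names and which was picked out for that reason after its value was seen, rose by 0.48 (SE 0.09, adjusted p = 1.91e-05) in the authors' deposited table.

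Of 19 thick filament and M-band genes, 6 rose, 3 fell and 10 did not pass (7 rose and 4 fell adjusted over the list alone; list adjusted p = 0.030). The call was lost without shared members (adjusted p = 0.0814), on ranks (adjusted p = 0.252), with a preset correlation of 0.05 (adjusted p = 0.109) and after the length and GC trend was removed (adjusted p = 0.185). Mybph (1.45, SE 0.20), Obsl1 (0.92, SE 0.13) and Myom3 (0.68, SE 0.09) rose and the methyltransferase gene Smyd2 fell by 0.60 on the log2 scale (SE 0.10) in the authors' deposited table. The muscle ankyrin repeat and stretch list passed (adjusted p = 0.0024): 5 of 13 rose, 1 fell and 7 did not pass (6 rose and 1 fell adjusted over the list alone). Ankrd1 (0.998, SE 0.22), the matrix protein gene Cilp (0.96, SE 0.11) and Ankrd23 (0.42, SE 0.09) rose, and Fhl3 (-0.71, SE 0.10) fell in the authors' deposited table. Costamere and dystrophin complex genes did not pass as a set (adjusted p = 0.097): 4 of 24 rose and 20 did not pass (5 rose adjusted over the list alone). The 4 in the authors' deposited table were Itga7 (0.53, SE 0.10), Tln1 (0.46, SE 0.09), Pxn (0.29, SE 0.10) and Itgb1bp2 (0.26, SE 0.09).

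Excitation-contraction coupling genes did not pass as a set (adjusted p = 0.24), with a mean of log2 0.09 and a median of -0.00117. Of 24, 4 rose, 3 fell and 17 did not pass (4 rose and 4 fell adjusted over the list alone). Sln, the slow calsequestrin Casq2 (0.57, SE 0.09) and Cacnb1 (0.56, SE 0.11) rose and Jph1 (-0.49, SE 0.09) fell in the authors' deposited table. Genes of the neuromuscular junction and of denervation were higher as a set (adjusted p = 2.82e-05): 7 of 20 rose, 1 fell and 12 did not pass (11 rose and 1 fell adjusted over the list alone). The adhesion molecule gene Ncam1 (1.05, SE 0.12), the acetylcholine receptor subunit Chrnb1 (0.94, SE 0.12), Myog and Runx1 (0.83, SE 0.19) rose in the authors' deposited table. The receptor kinase Musk fell there (-0.41, SE 0.14), and the subunits Chrna1 (0.09, SE 0.10) and Chrnd (0.02, SE 0.15) did not pass.

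Transcripts of the respiratory chain and of glycolysis were lower on the mKO side. Of 80 nuclear-encoded respiratory chain genes, none rose, 66 fell and 14 did not pass (71 fell adjusted over the list alone), with a median of log2 -0.39 and a list adjusted p of 4.60e-35. The smallest p-values in the authors' deposited table were those of Ndufa4 (-0.61, SE 0.09), Ndufv2 (-0.58, SE 0.10), Cox7b (-0.55, SE 0.09) and Uqcrb (-0.53, SE 0.09). Of 13 mitochondrially encoded transcripts, 12 fell and 1 did not pass (13 fell adjusted over the list alone; median -0.64, list adjusted p = 5.75e-13). Removal of the length and GC trend moved the list's mean difference in Wald statistic from the other genes from -4.43 to -2.73 (adjusted p = 3.84e-06). ND5 (-0.72, SE 0.13), ND1 (-0.68, SE 0.13), CYTB (-0.68, SE 0.12) and COX1 (-0.67, SE 0.11) gave the smallest p-values of these in the authors' deposited table. Glycolysis and glycogen genes fell too: 13 of 22 fell, none rose and 9 did not pass (15 fell adjusted over the list alone; median -0.34, list adjusted p = 5.07e-13). Examples in the authors' deposited table were Pfkfb1 (-0.99, SE 0.13), muscle enolase Eno3 (-0.71, SE 0.08), lactate dehydrogenase Ldha (-0.65, SE 0.08) and Aldoa (-0.62, SE 0.09). Of 24 fatty acid uptake and oxidation genes, 7 fell, none rose and 17 did not pass (9 fell adjusted over the list alone; list adjusted p = 0.0024). The median of this list, -0.11, lay at percentile 29.8 of 10000 random lists matched on mean normalized count, so it did not stand apart by that measure. Among those that fell were Lpl (-0.49, SE 0.11), Hadh (-0.40, SE 0.08), Etfa (-0.38, SE 0.10) and Acadm (-0.33, SE 0.08) in the authors' deposited table.

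The stress pathways moved in different directions. Integrated stress response genes, the targets and factors of the Atf4 branch, were lower as a set (adjusted p = 1.81e-06): 8 of 20 fell, none rose and 12 did not pass (11 fell adjusted over the list alone). Mthfd2 (-1.64, SE 0.20), the proline synthesis enzyme Aldh18a1 (-1.11, SE 0.18), Atf5 and Atf4 itself (-0.57, SE 0.09) fell in the authors' deposited table, while Asns (-0.06, SE 0.22) and Psat1 (0.14, SE 0.19) did not pass. Cytosolic heat shock proteins were higher as a set (adjusted p = 3.87e-07): 7 of 23 rose, 2 fell and 14 did not pass (9 rose and 2 fell adjusted over the list alone). Hspa1b (1.39, SE 0.16), Hspa1a (1.17, SE 0.14), Hspa2 (1.10, SE 0.14) and Bag3 rose in the authors' deposited table. Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. The 2 that fell there, Hspe1 (-0.36, SE 0.11) and Hspd1 (-0.27, SE 0.10), encode the mitochondrial chaperonin. None of 18 endoplasmic reticulum chaperones passed (none adjusted over the list alone; list adjusted p = 0.36), and Herpud1 had the smallest p at -0.23 (SE 0.10) in the authors' deposited table.

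Protein turnover lists did not pass. None of 37 proteasome subunits passed (none adjusted over the list alone; list adjusted p = 0.23), with Psmb7 at -0.23 (SE 0.09) in the authors' deposited table. Of 20 atrophy genes, 1 fell and 19 did not pass (1 fell adjusted over the list alone; list adjusted p = 0.51). The one that fell, myostatin (Mstn, -0.86, SE 0.23 in the authors' deposited table), is a growth inhibitor and not a ubiquitin ligase, and the ligases Fbxo32 (-0.05, SE 0.11) and Trim63 (-0.22, SE 0.12) did not pass there. Of 22 autophagy and lysosome genes, 5 rose, 1 fell and 16 did not pass (5 rose and 2 fell adjusted over the list alone; list adjusted p = 0.36). Ctsz (0.47, SE 0.12), Map1lc3a (0.37, SE 0.12) and Gaa (0.31, SE 0.09) rose and Map1lc3b (-0.29, SE 0.09) fell in the authors' deposited table. Of 76 cytosolic ribosomal protein genes, 1 fell, Rps27l (-0.33, SE 0.11 in the authors' deposited table), and 75 did not pass (none adjusted over the list alone; list adjusted p = 0.097).

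Of 14 p53 targets, 1 rose, 2 fell and 11 did not pass (1 rose and 2 fell adjusted over the list alone; list adjusted p = 0.3): Sesn1 (0.32, SE 0.11) rose and Cdkn1a (-0.45, SE 0.15) and Ei24 (-0.30, SE 0.09) fell in the authors' deposited table. Of 16 oxidative stress genes, 1 rose, 2 fell and 13 did not pass (1 rose and 3 fell adjusted over the list alone; list adjusted p = 0.21). Catalase (Cat, 0.30, SE 0.09) rose and Nqo1 (-0.56, SE 0.11) and Sod2 (-0.42, SE 0.08) fell in the authors' deposited table. Retinoic acid and Wnt signalling were listed because Hectd1 has been linked to both. Of 15 retinoic acid genes, 3 rose, 2 fell and 10 did not pass (4 rose and 2 fell adjusted over the list alone; list adjusted p = 0.59), including Rara (0.48, SE 0.13), Tgm2 (0.45, SE 0.10), Aldh1a1 (-0.52, SE 0.11) and Rxrg (-0.63, SE 0.14) in the authors' deposited table. Of 13 Wnt targets, 1 fell, Dkk2 (-0.83, SE 0.12 in the authors' deposited table), and 12 did not pass (1 fell adjusted over the list alone; list adjusted p = 0.97).

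Extracellular matrix genes were higher on the mKO side. Of 29, 19 rose, none fell and 10 did not pass (25 rose adjusted over the list alone), with a median of log2 0.58 and a list adjusted p of 6.22e-16. Thrombospondin 1 (Thbs1, 1.09, SE 0.14), the gelatinase Mmp2 (0.80, SE 0.14), Col3a1 (0.75, SE 0.12) and Col6a3 (0.64, SE 0.11) rose in the authors' deposited table. Markers of tendon cells, which make up tissue adjoining the muscle, were higher with them. Of 8 tenocyte markers, 7 rose and 1 did not pass (7 rose adjusted over the list alone; median 0.91, list adjusted p = 1.77e-12), with Comp at 1.42 (SE 0.18), Fmod at 1.15 (SE 0.14), Thbs4 at 1.06 (SE 0.12) and Tnmd at 0.98 (SE 0.16) in the authors' deposited table. Of 18 macrophage and myeloid markers, 5 rose and 13 did not pass (7 rose adjusted over the list alone; list adjusted p = 2.24e-04), among them C1qa (0.71, SE 0.18), C1qc (0.64, SE 0.18), Csf1r (0.58, SE 0.17) and Lyz2 (0.52, SE 0.11) in the authors' deposited table.

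Other cell types followed no single direction. Of 8 adipocyte markers, 5 rose, 1 fell and 2 did not pass (5 rose and 1 fell adjusted over the list alone; list adjusted p = 5.03e-04). Cidec (1.19, SE 0.21), Cfd (0.99, SE 0.15), Plin1 (0.94, SE 0.21) and Adipoq (0.90, SE 0.19) rose in the authors' deposited table, and the one that fell was Fabp4 (-0.38, SE 0.11), which capillary endothelium also makes. Of 12 fibro-adipogenic progenitor markers, 2 rose, 1 fell and 9 did not pass (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.033). That call was lost without shared members (adjusted p = 0.0585) and with a preset correlation of 0.05 (adjusted p = 0.0943). Sfrp4 (0.73, SE 0.21) and Dpp4 (0.71, SE 0.20) rose, Ly6a (-0.34, SE 0.09) fell and Pdgfra was at 0.04 (SE 0.15) in the authors' deposited table. Of 12 endothelial markers, 4 fell and 8 did not pass (4 fell adjusted over the list alone; list adjusted p = 0.0052): Emcn (-0.43, SE 0.13), Flt1 (-0.36, SE 0.11), Tie1 (-0.34, SE 0.10) and Pecam1 (-0.32, SE 0.12) in the authors' deposited table. Of 10 smooth muscle and pericyte markers, 1 rose (Cspg4, 0.77, SE 0.11), 2 fell (Rgs5, -0.38, SE 0.13, and Myh11, -0.33, SE 0.11, in the authors' deposited table) and 7 did not pass (1 rose and 2 fell adjusted over the list alone; list adjusted p = 0.66). None of 10 Schwann cell markers (list adjusted p = 0.48; Mbp at -0.37, SE 0.14) and none of 5 red blood cell markers (list adjusted p = 0.51; Hbb-bt at -0.28, SE 0.18) passed in the authors' deposited table, nor did any adjusted over the list alone. Of 12 lymphocyte markers, 2 had an adjusted p, too few for the same test, and over all listed genes the 7 listed markers did not pass as a set (adjusted p = 0.713).

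The lists fixed to show differences in collection did not pass. Of 17 circadian clock genes, 2 rose, Cry2 (0.51, SE 0.10) and Bhlhe41 (0.50, SE 0.11) in the authors' deposited table, and 15 did not pass (2 rose adjusted over the list alone; list adjusted p = 0.36). Of 15 immediate early genes, 3 rose, 1 fell and 11 did not pass (3 rose and 2 fell adjusted over the list alone; list adjusted p = 0.4): Junb (0.79, SE 0.15), Fosl2 (0.49, SE 0.15) and Jun (0.42, SE 0.11) rose and Btg2 (-0.55, SE 0.15) fell in the authors' deposited table.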

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

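The thresholds of 0.01 and 0.1, the lists without shared members and the 2 and 10 Mb windows were planned, and the other alternatives were chosen after seeing the data. The count of 1882 changed genes fell to 1192 at an adjusted p of 0.01, to 658 with a deposited fold change of at least 1.5 and to 326 with the inflation-corrected statistic, all 3 being stricter by construction. The share of changed genes that rose, 51.5%, lay between 49.4% (mean normalized count of at least 100) and 66.4% (fold change minimum) under the alternatives, so neither direction holds the majority under all of them. A turned contrast would make each the share that fell. A mean normalized count of at least 100 gave 1679 genes, protein-coding genes alone 1825, an adjustment over all listed genes 1838 and an adjusted p of 0.1 gave 2409. Hectd1 lay at log2 0.574 to 0.632 on the mKO side under the alternatives tried, with an inflation-corrected adjusted p of 0.0144. These shift or re-adjust the same deposited value, so they do not test its direction. Of the 139 named genes, 50 lost their call with the inflation-corrected statistic, whose factor also contains real effects, among them the 4 named macrophage genes (adjusted p from 0.116 to 0.417), the 4 endothelial genes (adjusted p from 0.426 to 0.632) and the 4 fatty acid genes (adjusted p from 0.0915 to 0.242), and none did with the adjustment over all listed genes. The number of lists past the threshold stayed between 16 and 19. The thick filament list lost its call under 4 of the 5 alternatives (adjusted p from 0.0814 to 0.252 in these), the Z-disc list under 3 and the fibro-adipogenic progenitors under 2. The nemaline list passed without shared members, and the ribosomal proteins passed as lower on ranks (adjusted p = 0.0105). No list that had passed changed direction. The percentile of a list's median among matched random lists did not always go with the set test. The fatty acid list passed at percentile 29.8. Lists that did not pass could lie at extreme percentiles, among them Schwann cell markers (0.69), p53 targets (1.66) and nemaline myopathy genes (99.04).

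No paired analysis was possible because the replicate numbers of the labels could not be tied to any column of values. For the same reason these were set out before the data were examined but not run: other normalizations, low-count filters, DESeq2 and limma-voom on the counts, leaving out mitochondrial genes, leaving out each replicate, the fold-change threshold test, estimated correlations and the rotation test. Other splits of the samples could not be counted either. What depth limits in single libraries is not known here.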

Other observations

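7 gene lists were chosen after the data were seen, and their calls are not independent of that choice. Nuclear-encoded parts of mitochondria outside the respiratory chain were lower on the mKO side too. Of 78 mitochondrial ribosomal proteins, 32 fell, none rose and 46 did not pass (46 fell adjusted over the list alone; list adjusted p = 2.81e-15), and of 19 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 15 fell and 4 did not pass (17 fell adjusted over the list alone; list adjusted p = 7.27e-14), with Idh3a at log2 -0.55 (SE 0.11) and Pdha1 at -0.52 (SE 0.09) in the authors' deposited table. Of 23 mitochondrial import genes, 6 fell and 17 did not pass (10 fell and 1 rose adjusted over the list alone; list adjusted p = 4.06e-04). Tubulins and microtubule proteins were higher as a set (9 of 24 rose, 2 fell; 11 rose and 2 fell adjusted over the list alone; list adjusted p = 0.0013): Tuba1c rose by 1.29 (SE 0.18) and Tubb4b by 0.72 (SE 0.12), while Tuba4a fell by 0.78 on the log2 scale (SE 0.09) in the authors' deposited table. Of 11 polyamine genes, 2 fell and 9 did not pass (4 fell adjusted over the list alone; list adjusted p = 0.053). The 2 were Smox (-1.13, SE 0.17) and Amd1 (-0.74, SE 0.13) in the authors' deposited table. Of 23 HECT ligases, Hectd1 included, 2 rose, 1 fell and 20 did not pass (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.82).

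Some genes were picked out only after their values were seen. 3 neighbouring transcripts of the imprinted Snrpn region on chromosome 7 fell together in the authors' deposited table: Snrpn (-0.81, SE 0.11), Snurf (-0.84, SE 0.13) and Ipw (-0.89, SE 0.16). Snurf lies inside Snrpn on the same strand and fragments were counted for both, so these are not independent values. Ndn, an imprinted gene of the same region, was at 0.24 (SE 0.20) and did not pass. The largest fall of all genes with an adjusted p in the authors' deposited table was that of Csn1s2b, a casein gene, at -2.25 (SE 0.24) with a mean normalized count of 30.2, below the level minimum for named genes.

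The tests of the next 4 paragraphs on the direction of the contrast, without Egln3, on runs of neighbouring genes, on the share of myofibre RNA, on tendon tissue and on scaling were chosen only after the results were seen. The higher Hectd1 transcript on the mKO side is the value that most needs a second look. Fragments from an overlapping gene are argued against, since 0 other annotated genes share exonic bases with it on its strand. Flanking DNA of the targeted allele that raises the whole neighbourhood is argued against as well: the 33 other tested genes within 5 Mb had a median log2 fold change of -0.145, and none of them rose. This does not speak to flanking DNA that changes Hectd1 alone or lowers its neighbours. A contrast written in the opposite direction could give the log2 fold change of 0.58, and so could a gene whose undeleted exons are transcribed more in the knockout. These cannot be told apart, because no library could be tied to a genotype. If the contrast were inverted, every direction in the report would invert with it.

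Those neighbours were lower as a set (cameraPR p = 6.36e-04): 25 of 33 lay below 0 and 4 fell, among them Egln3 (-1.19, SE 0.10), Nubpl (-0.92, SE 0.17) and Arhgap5 (-0.39, SE 0.14) in the authors' deposited table, and 2700097O09Rik (-0.45, SE 0.13). The median was -0.25 for the 11 genes within 2 Mb and -0.094 for the 47 within 10 Mb. The cameraPR p-values of these windows were 0.0285 and 0.00861. Without Egln3, the gene with the largest statistic, the median was -0.144 (permutation p = 0.00388 against random genes). These p-values take the genes as independent or nearly so. Mir1892 (-0.19) lies within Sptssa (-0.18) on the same strand and may share its fragments, so not all values of the window are independent. Of 415 runs of 33 neighbouring genes across the genome, 0 had a mean Wald statistic as low as the -1.34 of the window with Egln3. Egln3 itself was at -11.4, and the runs were not compared without it. No explanation for this fall was tested.

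Tenocyte and matrix transcripts were higher on the mKO side. A lower share of myofibre RNA would by itself raise the markers of other cell types alike. As the only cause it is argued against by the endothelial markers, which were lower as a set (median -0.217, list adjusted p = 0.0052). The median of the tenocyte markers lay 1.13 above theirs (permutation p = 0.001). Both lists were picked with their directions known, so this permutation p adds no support. A part in the rise is not excluded. Adipocyte (median 0.823), macrophage (0.405) and fibro-adipogenic progenitor markers (0.322) were higher too, while smooth muscle (-0.13) and Schwann cell markers (-0.206) lay below 0 and did not pass as sets. More tendon carried along with some muscles could raise tenocyte and matrix transcripts, as could a change of matrix production within the muscle of the libraries labelled mKO. These cannot be told apart here: the rise of 7 of the 8 tenocyte markers is the pattern itself and speaks for neither, and values per library would be needed.

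Respiratory chain transcripts were lower on the mKO side. Transcript length or GC bias as the whole cause is argued against, since the median stayed at -0.356 after the trend was removed (list adjusted p = 4.49e-33). A lower share of myofibre RNA was not settled. Slow-fibre sarcomere genes lay 0.844 above the respiratory chain by median (permutation p = 2.00e-05), but were known to be higher when picked. Fast-fibre sarcomere genes, also of myofibres, had a median of -0.731. Myofibre transcripts thus did not all fall together, and their share cannot be read from these lists. Cytosolic ribosomal proteins had a median of -0.0555, so the fall was not shared by all transcripts. Scaling moved by a few abundant transcripts cannot be tested this way, because the deposited fold changes already centre near 0 (median 0.00242). The fall extends to other nuclear-encoded mitochondrial proteins, with a median of -0.272 for mitochondrial ribosomal proteins, a list chosen after the data were seen. It was uneven. Fatty acid uptake and oxidation genes were lower as a set (list adjusted p = 0.0024), but their median of -0.114 lay at percentile 29.8 of matched random lists. Of these 24 genes 17 did not pass, and of 23 mitochondrial import genes 17 did not pass. A hypothesis is that the libraries labelled mKO hold fewer transcripts of several parts of mitochondria. This may be a response of the muscle to the loss of Hectd1. The fall was found and tested on the same data and depends on the direction of the contrast, and a link to Hectd1 was not tested.

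A further hypothesis joins the lower integrated stress response genes to a lower output of the amino acid response as a whole, which would also lower cytosolic aminoacyl-tRNA synthetases. Their median was -0.136, and 9 of 20 fell and 11 did not pass (9 fell and 1 rose adjusted over the list alone; list adjusted p = 2.16e-04), with Gars at -0.49 (SE 0.10) and Cars at -0.48 (SE 0.11) in the authors' deposited table. These values go with the hypothesis. The list was, however, among those chosen after the data were seen, so its call is not an independent test. Other targets of the branch did not move with the synthetases. Asns was at -0.06 (SE 0.22) and Psat1 at 0.14 (SE 0.19) in the authors' deposited table, so the hypothesis may hold for part of the response only.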
